A study of Mus musculus with 12 samples.

How the data were processed

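The 12 samples were 10x Genomics 3′ single-cell RNA libraries of mouse liver leukocytes (strain label C57/Bl6J). Per the labels, leukocytes were pelleted in Percoll, red blood cells were lysed and 8000 cells were targeted with the 3′ v3 kit. For each library the authors deposited a matrix of raw UMI counts per gene and barcode, made with Cell Ranger 7.0.0 per the file headers. The barcode and feature lists deposited beside each matrix hold names (unit: other) and no measurement. The processing notes name Cell Ranger, Seurat and the genome build mm10. They state neither the annotation release nor whether intronic reads were counted nor how cells were called. The feature list of 32285 genes was the same in all 12 libraries, and the lowest total of a barcode was 500 UMIs. Between 2 libraries, 0.104% to 0.511% of barcodes were shared.

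Barcodes with at least 200 genes and at most 15% mitochondrial UMIs were kept, which left out 2.33% to 5.36% of the barcodes of the J2 libraries and 25.9% to 35.4% of those of the J1 libraries for having too few genes. Hemoglobin made up most of the UMIs of those barcodes, with library medians of 78.5% to 90.8%. Between 54 and 634 barcodes per library were over the mitochondrial limit. Doublets were called per library with scanpy's implementation of Scrublet at an expected rate of 8%, and 4974 were removed (2.39% to 7.32% of a library). The counts were not corrected for free RNA. The 91178 cells left were scaled to their library size and log-transformed, and 2000 variable genes, 40 principal components and a graph of 20 neighbours entered Leiden clustering at resolution 1.0 with seed 1, which gave 48 clusters. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6 and scipy 1.17.1 were used, and matplotlib 3.10.9 drew the figures.

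Clusters were named from 18 marker sets by the highest mean log2 ratio of a set's markers to all other cells, with 20 CPM added to both. A name needed at least 3 markers found in at least 10% of the cluster's cells and raised at least 2-fold, and no other set with more markers among the cluster's 10 genes of largest fold. A cluster with few UMIs for its libraries and none of its class's markers among these 10 genes stayed unnamed too, which applied to cluster 35 (median 0.276 of the library medians). A pair of naming rules was set after the clusters were seen. Clusters in which at least 25% of cells had each of the genes Cd3e, Cd3d and Cd3g could not be named NK/ILC1 or ILC2, and clusters whose median doublet score reached the lowest library threshold stayed unnamed. In all 9 clusters stayed unnamed. The Kupffer cell and monocyte-derived macrophage names rest on markers alone, and the latter was a single cluster, 5, led by Cxcl9, Cxcl10, Lpl, F10 and Mmp14.

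UMIs were summed per library and class, for each of the 8 classes with at least 20 cells in every library. The sums were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, its quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment within each class at 0.05. The 12 libraries entered as 6 groups of 2, which share 1 estimate of spread with 6 residual degrees of freedom. The contrasts were CRE minus GFP, FLPO minus GFP and FLPO minus CRE, each the mean of the differences within J1 and within J2, J2 minus J1 as the mean of the differences within the 3 title labels, and the interactions of CRE minus GFP and of FLPO minus GFP with the suffix. The replicate numbers were not used to pair libraries, since the correlation of their deviations between groups lay from -0.06 to 0.19. Mapk8 and Mapk9 were also tested in the sum over all kept cells. CPM is edgeR's count of a gene relative to the TMM-scaled total of its class sum, and values in CPM are the mean of libraries with their SD.

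Shares of cells per class were tested with edgeR's quasi-likelihood test on the number of cells, with the library's kept cells as offset, for the 13 classes that averaged at least 10 cells a library, and adjusted over classes. An exact permutation of the title labels within each suffix on the log2 share was run beside it. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, where at least 5 members were tested, and adjusted over all lists and classes of a contrast. The 24 lists covered signalling, stress, inflammation, metabolism, cell functions and RNA of other cells. A sex-linked check among them gave no result, because in no class were 5 of its members tested.

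Genes were named by a rule. It takes Mapk8 and Mapk9 everywhere. Per class and contrast it takes up to 4 higher and 4 lower called genes with the largest change and the same sign within both suffixes (for J2 minus J1, within all 3 title labels), without predicted genes and antigen receptor V segments. Per called list it takes up to 4 members with the smallest p, per interaction up to 2 genes a class with the smallest adjusted p, and in a class without a call the gene with the smallest p. Above 30 genes in a contrast, the 30 with the largest change are named. Genes outside the rule are named as chosen after their values were seen. Some genes are not reported here. The groups, contrasts, tests, markers, lists, naming rule and the alternatives that follow were set before the data were examined.

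The alternatives for genes were DESeq2 1.42.0, median-ratio (RLE) factors, no filter on low counts, the replicate number as a block (4 residual degrees of freedom), an additive model, each library left out in turn, doublets kept, cells with at least 500 genes and at most 10% mitochondrial UMIs, Leiden resolution 0.5 (31 clusters) and 2.0 (64 clusters), and J1 and J2 in fits of their own. For shares they were leukocyte classes alone as denominator, TMM factors on cell counts, and the block, library, doublet, cell and resolution alternatives above. For lists they were an estimated correlation, fry, the block and each library left out. Chosen after the data were seen were the interaction and within-suffix tests of shares, fits without both of the libraries with the highest interferon lists, CRE_J1 replicate 2 and GFP_J2 replicate 1, list tests with the libraries in 5 shuffled orders, and the share of NK/ILC1 with clusters 23 and 28 counted in. The order matters because each gene has its own voom weights, so the residuals from which fry and the estimated correlation are computed change with it.

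Data simulated from these libraries had changes added to 200 genes. Of the 2-fold changes, CRE minus GFP found 86.7% in B cells and 85.3% in neutrophils, and J2 minus J1 89.7% in B cells. Real rates may be lower, since a larger difference, of Spp1, did not pass. The CRE interaction in neutrophils found 12.5% of 2-fold and 76.8% of 4-fold changes, so it missed most 2-fold ones. Interactions in other classes were not simulated. Replicate libraries were no copies: their counts differed by more than counting noise in every group (chi-square per degree of freedom 12.6 to 182.9). The share of 31-base words in the last 300 bases of a gene's transcripts found in another gene was computed from the mm10 reference. Genes with at least 30% were taken to have a near-identical copy. Of the genes, 32132 (99.53%) were matched to transcripts.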

Results

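The data held 12 single-cell libraries of leukocytes isolated from mouse liver, in 6 groups of 2 libraries. Each title joined 1 of 3 labels, GFP, CRE or FLPO, with the suffix J1 or J2 and a replicate number. GFP is the name of a fluorescent protein, and CRE and FLPO are the names of recombinases that join DNA at lox and FRT sites; the labels did not say how they were used here. The genotype label read J1 J2 lf/lf for all 12 libraries, the suffix was not explained, and no library was labelled with a diet. The series asks how a high-fat diet changes the immune cells of the liver and names a JNK isoform, so the comparisons below are between title labels and between suffixes and not between diets. Nothing states that the libraries came from separate animals, so every p-value here measures only the spread between libraries.

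The deposited matrices held 124624 barcodes and 857003831 unique molecular identifiers (UMIs). Total UMIs ran from 89928594 to 108562590 per J1 library and from 38184288 to 54689737 per J2 library. Hemoglobin genes took 12.9% to 25.5% of the UMIs of the J1 libraries and 0.318% to 0.838% of those of the J2 libraries. Of the barcodes, 91178 were kept as cells, 8222 to 9536 per J1 library and 5066 to 7845 per J2 library. The median kept cell had 6408.5 to 8333 UMIs in the J1 libraries and 4515.5 to 5372 in the J2 libraries. Clusters were named from marker genes, so each cell name below stands for a cluster with the markers of that cell. Of 48 clusters, 9 stayed without a class and the others fell into 13 classes. Gene changes were tested in 8 of these: B cell, T cell, NK/ILC1 (natural killer and innate lymphoid type 1 cells), neutrophil, monocyte, Kupffer cell (the resident liver macrophage), monocyte-derived macrophage and conventional dendritic cell. Kupffer cells were the fewest, with 26 to 104 cells per library.

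Mapk8 (ENSMUSG00000021936), which encodes the stress kinase JNK1, averaged 40.2 counts scaled to the library total (CPM) ± 0.721 (SD, n = 2) over all kept cells of GFP_J1. It averaged 33.5 ± 3.94 in CRE_J1 and 34.4 ± 1.09 in FLPO_J1, and 51.4 ± 1.59 in GFP_J2, 47.4 ± 2.06 in CRE_J2 and 57.9 ± 4.23 in FLPO_J2 (each SD, n = 2). Mapk8 was higher in J2 than in J1 by 0.54 on the log2 scale (SE 0.05, adjusted p = 7.27e-05), with each of the 6 J2 libraries above each of the 6 J1 libraries. Annotation release, intron counting and cell calling are not stated for either suffix, so any J2 minus J1 result may reflect processing. None of the 3 pairings of the title labels passed the test: the log2 difference was -0.19 for CRE minus GFP (SE 0.06, adjusted p = 0.934), -0.03 for FLPO minus GFP (SE 0.06, adjusted p = 0.941) and 0.16 for FLPO minus CRE (SE 0.06, adjusted p = 0.597). Before adjustment over all genes, p was 0.0164 for CRE minus GFP and 0.0317 for FLPO minus CRE. Mapk9 (ENSMUSG00000020366), which encodes JNK2, lay between 33.2 and 44.7 CPM in the 12 libraries. Its log2 difference was 0.00 for CRE minus GFP (SE 0.08, adjusted p = 1.00), -0.06 for FLPO minus GFP (adjusted p = 0.865), -0.07 for FLPO minus CRE (adjusted p = 0.795) and 0.10 for J2 minus J1 (SE 0.07, adjusted p = 0.231). Between 1241 and 3066 UMIs per library stood behind each of the values of Mapk8 and Mapk9. Counts from the 3′ end of a transcript cannot show the exchange of an internal exon, so they cannot tell apart isoforms of either gene that differ in this way.

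Between CRE and GFP, the interferon-stimulated gene Ifit1 averaged 83.1 CPM ± 37.4 (SD, n = 4) in monocyte-derived macrophages of the CRE libraries. In those of the GFP libraries it averaged 37.1 ± 4.55 (SD, n = 4). All 4 CRE libraries lay above all 4 GFP libraries, yet the log2 difference of Ifit1, 1.13 (SE 0.23), did not pass the test over all genes (adjusted p = 0.808). Spp1 and Gpnmb differed by -2.91 and -2.11 in the same cells (both adjusted p = 0.808). Ccl3, a chemokine, differed by -1.07 in neutrophils (SE 0.25, adjusted p = 0.383), an average of 0.38 in J1 (adjusted p = 0.968) and -2.51 in J2 (adjusted p = 0.012).

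No gene passed the CRE minus GFP test in any of the 8 classes by edgeR, over 87366 tests of a gene in a class. At an unadjusted p under 0.05 there were 5164, and DESeq2 called 32. The gene with the smallest p in each class, not called, was Lnx2 in B cells (-0.34), Ccr10 in T cells (-1.98), Cd160 in NK/ILC1 (0.56) and 2410006H16Rik in neutrophils (0.49). In the other classes it was Gm15448 in monocytes (-0.93), Nbea in Kupffer cells (2.57), Cnnm2 in monocyte-derived macrophages (-0.98) and Mamld1 in conventional dendritic cells (2.17).

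Lists of genes fixed in advance were ranked against all other genes of a class with limma's camera. For CRE minus GFP, 46 of 179 pairs of a list and a class were called, 33 higher and 13 lower, and none held with an estimated correlation (lowest adjusted p = 0.723), where 4 pairs lay under an unadjusted p of 0.05. By fry 0 were called and 7 lay under an unadjusted p of 0.05. The type I interferon response ranked higher in 7 classes, with its largest median log2 difference, 0.51, in monocyte-derived macrophages (adjusted p = 5.03e-19, or 0.938 with an estimated correlation). The CRE interaction of this list was also called, lower in J2 than in J1 in 8 classes (medians -1.41 to -0.33), though in none with an estimated correlation. In these macrophages all 27 members had a positive difference and 10 passed when adjusted over the list alone. CRE_J1 replicate 2 was the highest of the 12 libraries for this list in monocyte-derived macrophages (mean log2 level 7.31), and without it 4 of the 7 calls stayed, as they did without GFP_J2 replicate 2. Besides Ifit1, the members with the smallest p in those macrophages were Ddx58 (0.39), Usp18 (0.83) and Ifit3 (1.12). The lipid-associated macrophage list ranked lower in monocyte-derived macrophages, with a median of -0.52 and 18 of 18 members negative (adjusted p = 2.73e-06, or 0.938 with an estimated correlation), and lower in monocytes. The list of inflammatory cytokines and NF-kB targets ranked lower in monocytes and in neutrophils, where the median was -0.42 (adjusted p = 4.69e-06, or 0.938 with an estimated correlation). Cluster 16 made up 8.45% of the neutrophils of CRE_J2 and 39.3% of those of GFP_J2, and 29.8% and 22.3% of those of CRE_J1 and GFP_J1. In neutrophils 4 members passed when adjusted over the list alone, and those with the smallest p were Ccl3, Ccl4 (-0.97), Ptgs2 (-0.39) and Tnf (-0.76). Like Ccl3, Ccl4 and Tnf were higher in J1 (0.80 and 0.14) and lower in J2 (-2.74 and -1.66), and the CRE interaction of the list was called in 4 classes, lower in T cells, NK/ILC1 and neutrophils and higher in monocyte-derived macrophages (2 without CRE_J2 replicate 2), in none with an estimated correlation.

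Among the other lists, the interferon gamma response ranked higher for CRE in B cells, NK/ILC1, monocyte-derived macrophages and conventional dendritic cells. Oxidative phosphorylation ranked higher in 6 classes, and cytosolic ribosomal proteins higher in 5 and lower in Kupffer cells. CRE_J1 replicate 2 stood apart from the other J1 libraries in the interferon gamma response, oxidative phosphorylation and glycolysis, and without it 0 of 4, 1 of 6 and 0 of 3 calls of these lists stayed. Without CRE_J2 replicate 2, 1 of the 6 calls of cytosolic ribosomal proteins stayed and 0 of the 3 of glycolysis. The JNK pathway list ranked lower in B cells alone, where Map3k2, Map3k7 and Map2k4 differed by -0.13, -0.13 and -0.12 (adjusted p of the list 0.0112, or 0.886 with an estimated correlation), and this call ended without CRE_J2 replicate 2 or GFP_J2 replicate 1. Heat shock ranked lower in B cells, and glycolysis higher in B and T cells and lower in Kupffer cells. Immediate early/AP-1 genes ranked higher in Kupffer cells and lower in NK/ILC1 and monocytes. Clusters 1 and 6 made up 51.6% and 6.74% of the T cells of CRE_J2 against 39.7% and 15.1% of GFP_J2. Cell cycle ranked higher in T cells and lower in conventional dendritic cells, and T cell exhaustion and residency higher in NK/ILC1 and lower in neutrophils. Cluster 22 made up 23.5% and 73.6% of the NK/ILC1 cells of CRE_J1 and CRE_J2, and 16.5% and 50.2% of those of GFP_J1 and GFP_J2. Of the lists that follow RNA from other cells, neutrophil RNA ranked higher in monocytes, Kupffer cells and conventional dendritic cells. Hepatocyte RNA ranked higher in conventional dendritic cells and lower in monocytes, red blood cell RNA higher in conventional dendritic cells, and immunoglobulin RNA higher in B cells. The 7 other lists gave no call by camera. Leaving out some 1 library took at least 1 call from every called list but immunoglobulin RNA. Heat shock lost its only call without CRE_J1 replicate 1, CRE_J2 replicate 1, GFP_J1 replicate 2 or either GFP_J2 library, and red blood cell RNA without CRE_J2 replicate 2 or GFP_J2 replicate 2. Immediate early/AP-1 genes kept 1 of 3 calls without CRE_J1 replicate 2 or GFP_J2 replicate 1. The lipid-associated macrophage list and the inflammatory list each kept 1 of 2 calls, in macrophages and in neutrophils, without CRE_J1 replicate 2, CRE_J2 replicate 1 or GFP_J1 replicate 1, and the former also without GFP_J2 replicate 2, the latter without GFP_J2 replicate 1. Cell cycle kept 1 of 2 without either CRE_J1 library, CRE_J2 replicate 2, GFP_J1 replicate 2 or either GFP_J2 library. Hepatocyte RNA kept 1 of 2 without any 1 CRE library, GFP_J1 replicate 1 or GFP_J2 replicate 2. T cell exhaustion and residency kept 1 of 2 without any 1 library but CRE_J2 replicate 2 and FLPO_J2 replicate 1.

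The share of kept cells that were monocyte-derived macrophages averaged 4.06% ± 2.92 (SD, n = 4) in the CRE libraries and 5.35% ± 2.82 (SD, n = 4) in the GFP libraries, a log2 difference of -0.53 (SE 0.26) that did not pass the test and averages opposite changes, 1.10 in J1 (adjusted p = 0.115) and -2.16 in J2 (adjusted p = 0.0015). By edgeR 0 of 13 classes passed for CRE minus GFP, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.698. Exact permutation within suffix could call none: 36 relabelings allow no two-sided p under 0.0556 (lowest adjusted p = 0.889).

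Between FLPO and GFP, Fosb (ENSMUSG00000003545), an immediate early gene of the AP-1 factor, was lower in monocytes by -1.33 on the log2 scale (SE 0.13, adjusted p = 0.0052). It averaged 20.2 CPM ± 13.5 (SD, n = 4) in the FLPO libraries and 42.7 ± 3.57 (SD, n = 4) in the GFP libraries, and all 4 FLPO libraries lay below all 4 GFP libraries. In J1 Fosb averaged 45.3 ± 2.59 CPM in GFP and 8.98 ± 2.81 in FLPO (SD, n = 2; adjusted p = 0.00183), and in J2 40.01 ± 1.85 and 31.4 ± 6.40 (SD, n = 2; adjusted p = 0.51). The difference between the suffixes itself, 1.96, did not pass (adjusted p = 0.109). Fosb in monocytes no longer passed without GFP_J1 replicate 1 (-1.30, adjusted p = 0.0648), with the additive model (-1.18, adjusted p = 0.641) or with doublets kept (-1.06, adjusted p = 0.115).

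Fosb was the 1 gene called for FLPO minus GFP by edgeR over 87366 tests, with 5659 under an unadjusted p of 0.05 and 66 called by DESeq2. Elsewhere the gene with the smallest p, not called, was Dnajb1 in B cells (-0.81), Ide in T cells (0.40), Gm47283 in NK/ILC1 (-0.86) and Thbs1 in neutrophils (1.08). It was Igha in Kupffer cells (2.27), Fosb in monocyte-derived macrophages (-1.28) and Bag3 in conventional dendritic cells (-0.76).

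For FLPO minus GFP, camera called 54 of 179 pairs of a list and a class, 15 higher and 39 lower. With an estimated correlation it called 0 (lowest adjusted p = 0.808, 4 under an unadjusted p of 0.05), and fry called 0 (7 under an unadjusted p of 0.05). Heat shock ranked lower in 6 classes, with a median of -0.41 in B cells (adjusted p = 2.86e-15, or 0.808 with an estimated correlation), where 10 of 13 members were lower when adjusted over the list alone. The 2 GFP_J1 libraries were the highest of the 12 for heat shock in 8 of 8 classes, and the FLPO interaction of the list was called in 7 classes, higher in J2 than in J1, and in none with an estimated correlation. Without FLPO_J1 replicate 2, 4 of its 6 calls stayed. The members in B cells with the smallest p were Dnajb1, Hspa1a (-3.44), Dnaja1 (-0.46) and Hspa1b (-2.36), all chaperones or their partners. Immediate early/AP-1 genes ranked lower in B cells, T cells, monocytes and monocyte-derived macrophages and higher in Kupffer cells, and 2 of these 5 calls stayed without FLPO_J2 replicate 1 or GFP_J1 replicate 1. The type I interferon response ranked higher in B cells, T cells, Kupffer cells, monocyte-derived macrophages and conventional dendritic cells, and 2 of these 5 calls stayed without GFP_J2 replicate 2. Cytosolic ribosomal proteins ranked lower in all 8 classes, with medians from -0.19 to -0.11, and in monocytes 13 members were lower when adjusted over the list alone. The FLPO interaction was called for this list in 7 classes, lower in J2 in 6 (5 calls stayed without GFP_J2 replicate 1), and for immediate early/AP-1 genes in 6, higher in J2 (2 without FLPO_J2 replicate 2 or GFP_J1 replicate 1), none with an estimated correlation. Immunoglobulin RNA ranked higher in T cells, neutrophils, monocytes and monocyte-derived macrophages, the last led by Igha (1.73), and 2 of these 4 calls stayed without FLPO_J1 replicate 2, FLPO_J2 replicate 1, GFP_J1 replicate 2 or GFP_J2 replicate 2. The JNK pathway list ranked higher in neutrophils, with a median of 0.16 (adjusted p = 0.032, or 0.808 with an estimated correlation), a call that ended without FLPO_J1 replicate 1, either FLPO_J2 library, GFP_J1 replicate 2 or GFP_J2 replicate 2.

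Of the remaining lists for FLPO minus GFP, cell cycle and neutrophil RNA ranked higher in Kupffer cells, hepatocyte RNA higher in monocytes, and red blood cell RNA higher in conventional dendritic cells and lower in T cells and neutrophils. Glycolysis ranked lower in 4 classes, inflammatory cytokines and NF-kB targets in 3, and cholesterol synthesis in T cells and conventional dendritic cells. The interferon gamma response ranked lower in T cells and neutrophils, MHC class II in B cells and Kupffer cells, and oxidative phosphorylation in monocytes and conventional dendritic cells. Neutrophil RNA ranked lower in T cells and monocyte-derived macrophages, T cell exhaustion and residency in neutrophils, and the unfolded protein response in T cells. The T cells were a different mix: cluster 31 made up 6.89% of those of FLPO_J1 and 0.13% of GFP_J1, and clusters 6 and 8 25.4% and 9.00% of FLPO_J2 and 15.1% and 19.0% of GFP_J2. The 5 other lists gave no call by camera. Without GFP_J2 replicate 1, none of the calls of glycolysis (4), the interferon gamma response (2), MHC class II (2), neutrophil RNA (3), hepatocyte RNA (1) or the unfolded protein response (1) stayed. None stayed either without FLPO_J2 replicate 2 for the interferon gamma response and neutrophil RNA, without FLPO_J1 replicate 1 for MHC class II, cell cycle and hepatocyte RNA, or without FLPO_J2 replicate 1 for the unfolded protein response and hepatocyte RNA. Neutrophil and hepatocyte RNA also lost all calls without either CRE_J2 library, and hepatocyte RNA without GFP_J1 replicate 2 or GFP_J2 replicate 2. The inflammatory list kept 1 of 3 calls without GFP_J1 replicate 1, red blood cell RNA 1 of 3 without FLPO_J2 replicate 2, and T cell exhaustion and residency lost its call whichever of the 12 libraries was left out.

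Plasma cells took 1.48% ± 0.511 (SD, n = 4) of the kept cells of the FLPO libraries and 0.871% ± 0.592 (SD, n = 4) of those of the GFP libraries. Neutrophils took 6.06% ± 2.24 (SD, n = 4) and 8.58% ± 0.482 (SD, n = 4). Neither passed the edgeR test for FLPO minus GFP: the log2 difference was 0.90 for plasma cells (SE 0.36) and -0.57 for neutrophils (SE 0.23), both with an adjusted p of 0.187. Within J1 and J2 they were 1.99 and -0.20 for plasma cells and -0.97 and -0.17 for neutrophils. They were the 2 of 13 classes at an unadjusted p under 0.05. The exact permutation could call none by design (lowest adjusted p = 0.361).

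Between FLPO and CRE, where chance cannot be excluded, 4 genes passed in conventional dendritic cells. The FLPO libraries had more RNA of Cd36 (ENSMUSG00000002944), a lipid scavenger receptor, by 0.73 on the log2 scale (SE 0.09, adjusted p = 0.0208). They also had more of Plpp1 (ENSMUSG00000021759), a lipid phosphate phosphatase, by 0.80 (SE 0.11, adjusted p = 0.0264), and of Ppfibp2 (ENSMUSG00000036528), a liprin scaffold protein, by 0.64 (SE 0.08, adjusted p = 0.0210). Cebpb (ENSMUSG00000056501), a myeloid transcription factor, was lower in FLPO by -0.90 (SE 0.10, adjusted p = 0.00917); the list of neutrophil RNA also ranked lower in these cells. For all 4 genes, all 4 FLPO libraries lay on the same side of all 4 CRE libraries. Cd36 averaged 98.4 CPM ± 12.4 in FLPO and 59.2 ± 9.81 in CRE, and Cebpb 51.2 ± 10.3 and 95.1 ± 7.59 (SD, n = 4). Plpp1 averaged 61.9 ± 9.47 in FLPO and 35.4 ± 4.12 in CRE, and Ppfibp2 83.1 ± 18.4 and 52.7 ± 4.89 (SD, n = 4). Cebpb no longer passed without FLPO_J1 replicate 1 or 2 (adjusted p = 0.0587 and 0.0684). The calls of Cd36, Ppfibp2 and Plpp1 ended without either GFP_J1 library, either FLPO_J1 library, CRE_J2 replicate 1 or FLPO_J2 replicate 2 (0.58 to 0.82), Ppfibp2 also without FLPO_J2 replicate 1 and Plpp1 without CRE_J1 replicate 2. With the replicate number as a block, which leaves fewer residual degrees of freedom, Plpp1, Cd36 and Ppfibp2 no longer passed (adjusted p = 0.101, 0.101 and 0.0996). Plpp1 did not pass without both interferon-high libraries, CRE_J1 replicate 2 and GFP_J2 replicate 1 (0.76, adjusted p = 0.0677), and with doublets kept Cebpb did not (-0.66, adjusted p = 0.172).

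The other genes called were Thbs1 and Basp1 in neutrophils. Their FLPO minus CRE differences, 1.98 (SE 0.21, adjusted p = 0.00359) and 1.07 (SE 0.15, adjusted p = 0.0485), had opposite signs in the suffixes, so the naming rule left them out and they were chosen after their values were seen. The neutrophils compared were a different mix, with cluster 16 at 31.8% of FLPO_J2 and 8.45% of CRE_J2, and at 25.5% of FLPO_J1 and 29.8% of CRE_J1. In all, edgeR called 6 genes for FLPO minus CRE, 5 higher and 1 lower, over 87366 tests, with 9216 under an unadjusted p of 0.05 and 345 (106 higher, 239 lower) called by DESeq2. The count reached 888 (409 higher, 479 lower) without CRE_J1 replicate 1, 232 (37 higher, 195 lower) without CRE_J2 replicate 1 and 29 (11 higher, 18 lower) without GFP_J2 replicate 1 or without replicate 2. In the classes without a call, the gene with the smallest p was Timm13 in B cells (-0.39), Tuba1a in T cells (-0.36) and Rnf144a in NK/ILC1 (2.16). It was Fosb in monocytes (-0.97), Igha in Kupffer cells (1.38) and Tfec in monocyte-derived macrophages (-0.73).

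**Figure D1:**
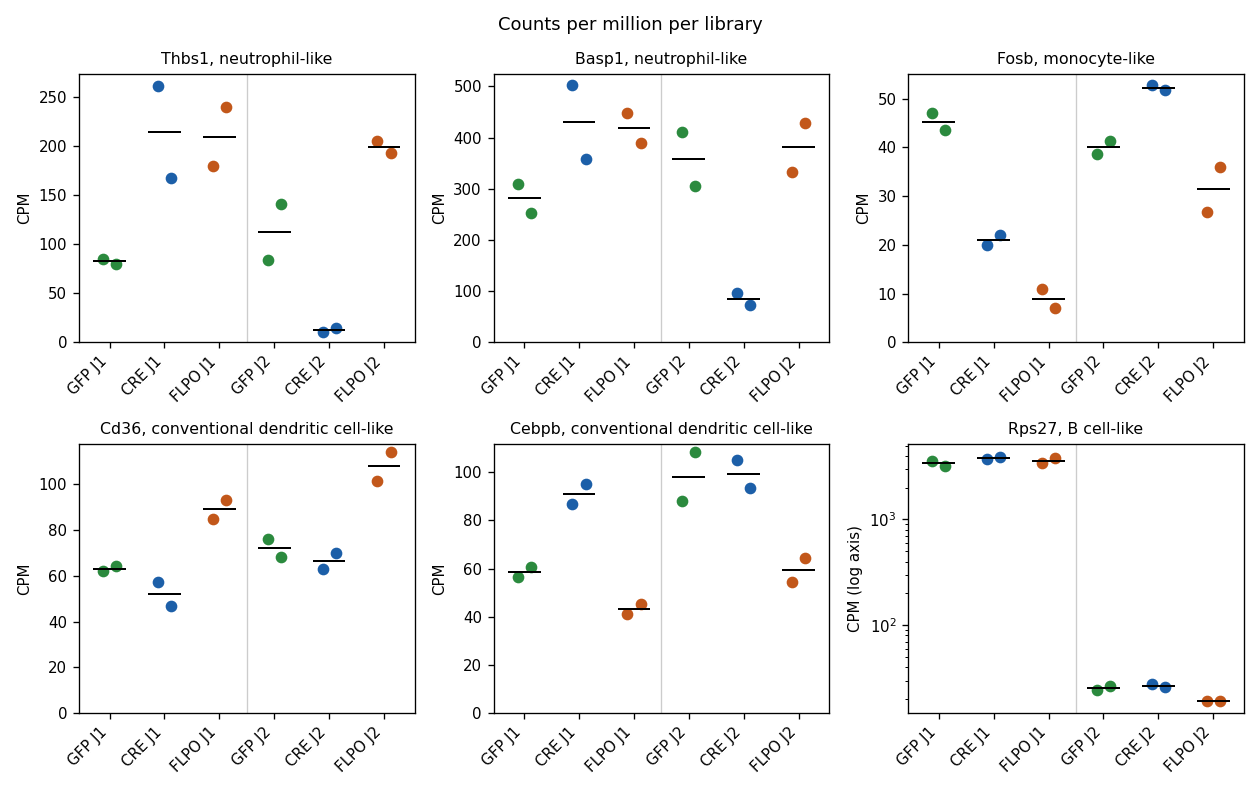
Expression (CPM) of 6 genes in the class named above each panel (Rps27 on a log axis) for the 6 groups; points are libraries and black lines group means. Thbs1 averaged 12.5 in CRE_J2 neutrophils against 112 in GFP_J2.

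For FLPO minus CRE, camera called 61 of 179 pairs of a list and a class, 12 higher and 49 lower. With an estimated correlation it called 0 (lowest adjusted p = 0.786, 6 under an unadjusted p of 0.05), and fry called 0 (17 under an unadjusted p of 0.05). The interferon gamma response ranked lower in all 8 classes, most in monocyte-derived macrophages with a median of -0.87 (adjusted p = 8.42e-07, or 0.786 with an estimated correlation), where 12 members were lower when adjusted over the list alone. It was led there by Socs1 (-1.998), Irgm1 (-0.89), Gbp5 (-1.42) and Iigp1 (-2.69). CRE_J1 replicate 2 was the highest of the 12 libraries for the interferon gamma response in monocyte-derived macrophages (mean log2 level 8.12, the others at most 7.45), and without it 1 of the 8 calls stayed, the one in these macrophages. The type I interferon response ranked lower in neutrophils, monocytes, monocyte-derived macrophages and conventional dendritic cells, and 2 of these 4 calls stayed without the same library. Cholesterol synthesis ranked lower in 5 classes, with a median of -0.37 in conventional dendritic cells, where the enzyme genes Fdps (-0.78) and Msmo1 (-0.52) were among the members with the smallest p. The lipid-associated macrophage list ranked higher in Kupffer cells, in monocyte-derived macrophages (median 0.69) and in neutrophils (median 0.26), and 5 of its members were higher in neutrophils when adjusted over the list alone. Of these 3 calls, only that in monocyte-derived macrophages stayed without CRE_J1 replicate 2, CRE_J2 replicate 1 or FLPO_J2 replicate 2, and 3 of the 5 calls of cholesterol synthesis stayed without CRE_J2 replicate 2.

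Oxidative phosphorylation ranked lower in FLPO than in CRE in 7 classes, and cytosolic ribosomal proteins lower in 7 and higher in Kupffer cells. Heat shock and glycolysis ranked lower in B cells, T cells and conventional dendritic cells, immediate early/AP-1 genes in B cells, T cells and monocyte-derived macrophages, and the unfolded protein response in B and T cells. The T cells were a different mix: clusters 1, 6 and 8 made up 34.7%, 25.4% and 9.00% of those of FLPO_J2 and 51.6%, 6.74% and 22.8% of those of CRE_J2, and cluster 31 6.89% of those of FLPO_J1, with 328 of its 331 cells there from replicate 1. CRE_J1 replicate 2 stood apart from the other J1 libraries in oxidative phosphorylation and glycolysis, and without it 6 of the 7 and 1 of the 3 calls stayed. Without CRE_J2 replicate 2, 1 of the 3 calls stayed for glycolysis and for heat shock, and without FLPO_J2 replicate 1, 0 of the 3 for immediate early/AP-1 genes. The unfolded protein response kept 1 of 2 without CRE_J1 replicate 2, CRE_J2 replicate 2, FLPO_J1 replicate 2 or FLPO_J2 replicate 1. Cytotoxic effectors and T cell exhaustion and residency ranked lower in NK/ILC1, MHC class II in B cells, and neutrophil RNA in monocyte-derived macrophages and conventional dendritic cells. Inflammatory cytokines and NF-kB targets ranked higher in neutrophils and lower in Kupffer cells, the JNK pathway higher in conventional dendritic cells, and cell cycle higher in these and in Kupffer cells. Hepatocyte and immunoglobulin RNA ranked higher in monocytes, and red blood cell RNA higher in B cells and conventional dendritic cells and lower in T cells. Cluster 22 made up 52.5% of the NK/ILC1 cells of FLPO_J2 and 73.6% of those of CRE_J2, and 26.0% and 23.5% of those of FLPO_J1 and CRE_J1, and the exhaustion call ended without CRE_J1 replicate 2 or CRE_J2 replicate 2. Cell cycle lost both calls without FLPO_J1 replicate 1 and the inflammatory list both without FLPO_J2 replicate 2. The immunoglobulin RNA call ended without CRE_J1 replicate 2, CRE_J2 replicate 1, FLPO_J1 replicate 2 or FLPO_J2 replicate 1, and red blood cell RNA kept 1 of 3 without CRE_J2 replicate 1, FLPO_J1 replicate 2 or FLPO_J2 replicate 2. The 3 other lists gave no call by camera. By edgeR 0 of 13 classes passed in their share of cells, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.138. The exact permutation could call none by design (lowest adjusted p = 0.642).

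Between J2 and J1 the monocytes took 20.9% ± 3.97 (SD, n = 6) of the kept cells of J2 and 6.93% ± 3.02 (SD, n = 6) of those of J1, a log2 difference of 1.66 (SE 0.19, adjusted p = 8.67e-06). NK/ILC1 cells took 2.08% ± 0.446 and 4.19% ± 1.16 (SD, n = 6), a difference of -1 (SE 0.21, adjusted p = 0.00137). With clusters 23 and 28 counted in, which a rule on Cd3 genes kept out, they took 4.30% ± 1.37 and 5.61% ± 1.55 (SD, n = 6) and did not pass (-0.40, SE 0.23, adjusted p = 0.199), a test chosen after the data were seen. Basophils and mast cells took 0.134% ± 0.0627 and 0.480% ± 0.210 (SD, n = 6), a difference of -1.71 (SE 0.34, adjusted p = 0.0013). Plasma cells took 1.22% ± 0.382 and 0.886% ± 0.753 (SD, n = 6), a difference of 0.86 (SE 0.29, adjusted p = 0.028) that no longer passed without GFP_J1 replicate 1, CRE_J1 replicate 2, either FLPO_J1 library, GFP_J2 replicate 2, CRE_J2 replicate 2 or FLPO_J2 replicate 1 (0.66 to 0.86). The title labels did not agree: plasma cells took 0.463% ± 0.0828 of GFP_J1, 0.351% ± 0.243 of CRE_J1 and 1.84% ± 0.0176 of FLPO_J1, against 1.28% ± 0.614 of GFP_J2, 1.27% ± 0.260 of CRE_J2 and 1.11% ± 0.4995 of FLPO_J2 (SD, n = 2). Hepatocytes differed by -3.70 (SE 0.88, adjusted p = 0.011) and erythroid cells by -6.40 (SE 0.30, adjusted p = 1.15e-09), neither of them leukocytes. Hepatocytes took 10.2% ± 8.34 (SD, n = 6) of the J1 and 0.688% ± 0.343 (SD, n = 6) of the J2 libraries. They ranged in J1 from 18.7% in FLPO_J1 replicate 1 to 0.778% in CRE_J1 replicate 2, which lay within the J2 range of 0.0510% to 0.996%. Erythroid cells took 3.93% ± 1.38 and 0.0517% ± 0.0377 (SD, n = 6) of the J1 and the J2 libraries. The hepatocyte share no longer passed without GFP_J2 replicate 1 or 2 or without FLPO_J2 replicate 1 (-3.63, -3.78 and -3.61). These 6 of 13 classes passed, 2 higher and 4 lower. Neutrophils and monocyte-derived macrophages, each 0.28 higher, did not pass.

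Rps27 (ENSMUSG00000090733), a protein of the small ribosomal subunit, was much lower in J2. It averaged 3615 CPM ± 271 (SD, n = 6) in J1 B cells and 23.8 ± 3.65 (SD, n = 6) in J2 B cells, a log2 difference of -7.26 (SE 0.08). Rps27 was lower in T cells by -7.82 and among the genes that changed most in NK/ILC1, monocytes, monocyte-derived macrophages and conventional dendritic cells, by -7.56 to -7.26. Rpl10 (ENSMUSG00000008682), of the large subunit, was lower in monocyte-derived macrophages by -7.02, from 2028 ± 113 to 15.5 ± 1.62 CPM (SD, n = 6). Hist1h3b, a replication-dependent histone, had 628 UMIs in J1 T cells and 1 in J2 T cells, a ratio of 319.3 (95% exact counting interval 57.1 to 12600). Gphn, which encodes the scaffold protein gephyrin, was lower in neutrophils by -7.14 (SE 0.17), from 1579 ± 127 to 11.3 ± 4.17 CPM (SD, n = 6). Rps27 and Rpl10 belong to 19 genes more than 4-fold lower in all 8 classes. Of these 78.9% had a near-identical copy, against 9.34% of other genes.

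The naming rule gave 64 J2 minus J1 results and kept the 30 with the largest change, 9 higher and 21 lower, of 19 distinct genes. Among them 11 had no UMI in 1 suffix, and against a floor of 3 counts over that suffix's 6 libraries they differed at least 15.5-fold to at least 110.8-fold. Cyp2c69, a cytochrome P450 with no UMI in J1, was at least 110.8-fold higher in J2 T cells and at least 76.7-fold in B cells. Vmn1r197, a pheromone receptor, was at least 77.5-fold higher in J2 B cells and at least 62.95-fold in T cells. The keratin gene Krt28 was at least 45.2-fold higher in J2 monocytes, and Pdzrn3, a ubiquitin ligase, at least 36.9-fold in monocyte-derived macrophages. With 2 UMIs in J1, Krt28 in B cells was 154.9-fold higher (95% exact counting interval 42 to 1290), the olfactory receptor gene Olfr77 in T cells 146.5-fold (39.9 to 1220) and the pheromone receptor gene Vmn2r7 in monocytes 88.7-fold (24.3 to 736). Grik3, with no UMI in J2, was at least 61.7-fold lower in J2 neutrophils and at least 48.1-fold in conventional dendritic cells. In monocyte-derived macrophages Grik3 was lower by -7.71. Ptprq was at least 23.2-fold lower in J2 T cells, and the histone genes Hist1h2ap and Hist1h3e at least 16.9-fold and at least 15.5-fold lower in J2 NK/ILC1. Hist1h3f had 298 UMIs in J1 and 1 in J2 B cells, a ratio of 127 (95% exact counting interval 22.6 to 5030), and Hist2h2aa1 was lower in T cells by -6.93. Intervals and floors cover counting error only, not processing differences. The remaining named genes encode hemoglobin: Hba-a1 was lower in NK/ILC1 by -6.98 and in Kupffer cells by -8.36, and Hba-a2 and Hbb-bt in conventional dendritic cells by -7.62 and -7.40.

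In total edgeR called 29424 of 87366 tests for J2 minus J1, 14117 higher and 15307 lower. B cells had 6754 of the calls, T cells 6401, monocytes 4849, conventional dendritic cells 4338, monocyte-derived macrophages 2847, NK/ILC1 2632, neutrophils 1390 and Kupffer cells 213. Classes differed in cells and genes tested, so these counts do not rank them. The mix differed: cluster 17 took 9.94% to 12.7% of the T cells of the J1 groups and 2.11% to 3.13% of those of the J2 groups, and cluster 15 at least 11.1% and at most 4.75% of their B cells. Gm20594 and Gm48099, 2 predicted genes, were more than 4-fold higher in all 8 classes.

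By camera 72 of 179 pairs of a list and a class were called for J2 minus J1, 13 higher and 59 lower. With an estimated correlation none was called (lowest adjusted p = 0.378, 22 under an unadjusted p of 0.05), and fry called 80. Red blood cell RNA ranked lower in all 8 classes (medians -7.53 to -5.13, 5 of 5 members called in each). Hepatocyte RNA ranked lower in 7 classes, with a median of -2.92 in B cells and 19 of 21 members called there. Cytosolic ribosomal proteins ranked lower in all 8 classes, with a median of -0.87 in T cells and 26 of 26 members called there. Heat shock ranked lower in all 8 classes, with a median of -0.81 in monocyte-derived macrophages; the 2 GFP_J1 libraries were the highest of the 12 in 8 of 8 classes, and both interactions of the list were called (6 and 7 classes, none with an estimated correlation). Immediate early/AP-1 genes ranked higher in Kupffer cells (median 0.71), neutrophils (0.50), conventional dendritic cells (0.48), monocytes (0.27) and monocyte-derived macrophages (0.23). The JNK pathway list ranked higher in monocytes (median 0.26), monocyte-derived macrophages (0.24), conventional dendritic cells (0.24) and T cells (0.21). MHC class II ranked lower in T cells (-0.88), monocytes (-0.63) and Kupffer cells (-0.63).

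Glycolysis ranked lower in J2 in 7 classes, oxidative phosphorylation in 6, the type I interferon response in 5 and the unfolded protein response in 4. Of the calls of these last lists, 3 of 5 stayed without CRE_J1 replicate 2, GFP_J1 replicate 2 or GFP_J2 replicate 2, and 2 of 4 without CRE_J1 replicate 2, CRE_J2 replicate 1, FLPO_J1 replicate 1 or FLPO_J2 replicate 1. Cholesterol synthesis ranked higher in T cells and neutrophils, inflammatory cytokines and NF-kB targets higher in Kupffer cells, and T cell exhaustion and residency higher in NK/ILC1. Fatty acid oxidation ranked lower in NK/ILC1, of which cluster 22 made up 16.5% to 26.0% in the J1 groups and 50.2% to 73.6% in the J2 groups, and the lipid-associated macrophage list and neutrophil RNA lower in neutrophils. The call of the lipid-associated macrophage list ended without CRE_J1 replicate 1 or FLPO_J2 replicate 1, and that of neutrophil RNA without replicate 2 of CRE_J1, CRE_J2, FLPO_J1 or GFP_J1. The interferon gamma response, cell cycle, cytotoxic effectors, fibrosis-linked secreted factors, immunoglobulin RNA and p53 targets gave no call by camera.

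Whether the title labels differed in the same way in both suffixes was tested as an interaction, CRE minus GFP in J2 less CRE minus GFP in J1. In neutrophils Thbs1 (ENSMUSG00000040152) had an interaction of -4.53 on the log2 scale (SE 0.42, adjusted p = 9.1e-04). In J2 it averaged 12.5 CPM ± 3.18 (SD, n = 2) in CRE and 112 ± 40.5 in GFP, and in J1 215 ± 66.2 in CRE and 82.7 ± 3.38 in GFP (each SD, n = 2). Within J2 the CRE minus GFP difference of Thbs1 was -3.16 (adjusted p = 0.00277) and within J1 1.37 (adjusted p = 0.872). Basp1 (ENSMUSG00000045763) had an interaction of -2.69 (SE 0.31, adjusted p = 0.00429), with 84.6 CPM ± 15.5 (SD, n = 2) in CRE_J2 and 357.5 ± 74.9 (SD, n = 2) in GFP_J2 neutrophils. Ccl3 (-2.89, adjusted p = 0.0256) and Cxcl2 (-2.47, adjusted p = 0.0285), both chemokines, moved the same way. So did Il1rn (-2.13, adjusted p = 0.0186) and Slc7a11 (-2.10, adjusted p = 0.0215). These 4 were chosen after their values were seen. Cluster 16 made up 8.45% of the neutrophils of CRE_J2 and 22.3% to 39.3% of those of the other groups.

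The CRE interaction called 121 genes, 19 higher and 102 lower, with 9462 under an unadjusted p of 0.05. Of these 108 were in neutrophils (13 higher, 95 lower) and 9 in NK/ILC1. The count was 7 without GFP_J1 replicate 2, 13 without GFP_J1 replicate 1, 15 without GFP_J2 replicate 1 and 703 without CRE_J1 replicate 1. It was 552 without GFP_J2 replicate 2, 196 without CRE_J1 replicate 2, 41 (21 higher, 20 lower) without CRE_J2 replicate 1 and 52 (31 higher, 21 lower) without replicate 2. Without FLPO_J1 replicate 1 or 2 it was 65 each time. In NK/ILC1 the interaction was 3.08 for Atp8a2 (SE 0.36, adjusted p = 8.4e-04), and -2.93 for Cx3cr1 (SE 0.47, adjusted p = 0.0368). Cluster 22 made up 73.6% of the NK/ILC1 cells of CRE_J2, 50.2% of GFP_J2, 23.5% of CRE_J1 and 16.5% of GFP_J1. In monocyte-derived macrophages Tfec had an interaction of 1.64 (SE 0.20) and Syne1 3.54 (SE 0.43), both with an adjusted p of 0.0347. Igkc, an antibody light chain, had 3.49 in Kupffer cells (SE 0.46, adjusted p = 0.0127), and Hbb-bs, a hemoglobin chain, 4.23 in conventional dendritic cells (SE 0.51, adjusted p = 0.0366). Both are genes of other cells, whose free RNA was not corrected for. By camera, though in none with an estimated correlation, the CRE interaction called red blood cell RNA higher in T cells, NK/ILC1, monocytes and conventional dendritic cells, and immunoglobulin RNA higher in T cells, monocyte-derived macrophages and conventional dendritic cells and lower in B cells. Of each 4 calls, 1 stayed for the former without CRE_J2 replicate 2 or GFP_J2 replicate 2 and 0 for the latter without CRE_J1 replicate 2. With 1 library left out, Cx3cr1 was no longer called without either GFP_J1 library, GFP_J2 replicate 1, CRE_J2 replicate 2 or either FLPO_J2 library (-2.97 to -2.54), and Igkc without GFP_J1 replicate 1, either GFP_J2 library or CRE_J2 replicate 1 (3.15 to 3.82). Tfec kept its call only without CRE_J1 replicate 1, and Syne1 only without either CRE_J1 library. Hbb-bs lost its call without any 1 FLPO or GFP_J2 library or GFP_J1 replicate 2 (3.73 to 4.78). Doublets kept ended the calls of Cx3cr1 (-2.63), Tfec (1.54), Syne1 (2.91) and Hbb-bs (adjusted p = 0.279), the replicate block those of Tfec (1.63) and Syne1 (3.55), and leaving out both interferon-high libraries those of Cx3cr1 (adjusted p = 0.37) and Hbb-bs (4.81). At Leiden resolution 0.5 Igkc (6.50) and Hbb-bs (3.26) were not called, and at 2.0 Tfec (0.76) and Hbb-bs (4.71) were not. In classes without a call the smallest p belonged to Ralgds in B cells (0.98), S100a4 in T cells (-1.60) and Fosb in monocytes (1.498). Cluster 1 made up 51.6% of the T cells of CRE_J2, 39.7% of GFP_J2, 24.5% of CRE_J1 and 32.5% of GFP_J1. Within J1 CRE minus GFP called 19 genes over the 8 classes and within J2 194. Of the latter 188 were in neutrophils, and without cluster 16 none of these was called, with a median log2 difference in their own direction of 0.40 against 1.29. Without both interferon-high libraries CRE minus GFP in J2 called 201, of which 81 were in neutrophils and 117 in monocyte-derived macrophages (78 higher, 39 lower).

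The FLPO interaction called 3 genes, 1 higher and 2 lower, with 5461 under an unadjusted p of 0.05. They were Gm47283 in NK/ILC1 (-1.98, SE 0.31, adjusted p = 0.0444), and Hbb-bs (4.47, SE 0.51) and Mmp25 (-1.93, SE 0.23) in conventional dendritic cells (both adjusted p = 0.0124). The FLPO interaction also called red blood cell RNA higher in 5 classes and immunoglobulin RNA lower in 5 (3 without FLPO_J1 replicate 2), none with an estimated correlation. The count was 0 without FLPO_J1 replicate 1 or 2 or without FLPO_J2 replicate 2. It was 10 and 11 without CRE_J1 replicates 1 and 2, and 13 and 11 without CRE_J2 replicates 1 and 2. Gm47283 (-2.22 to -1.62) and Mmp25 (-2.03 to -1.82) lost their calls without GFP_J1 replicate 1, any 1 FLPO library or either GFP_J2 library, and Hbb-bs without any 1 FLPO library or either GFP_J2 library (4.02 to 5.02). With doublets kept Gm47283 (-1.87) and Hbb-bs (2.74) were not called, at Leiden resolution 0.5 Hbb-bs (3.52) was not, and without both interferon-high libraries none of the 3 was (-1.85, 5.03 and -1.87). Not called but with the smallest p were Igha in B cells (-2.67, adjusted p = 0.051) and in neutrophils (-2.69), Btaf1 in T cells (0.77) and Fosb in monocytes (1.96). In Kupffer cells it was mt-Nd3 (1.44) and in monocyte-derived macrophages Hist1h1e (-1.77). Within J1 FLPO minus GFP called 29 genes and FLPO minus CRE 7, and within J2 2 and 187 (153 higher, 34 lower). Without both interferon-high libraries these were 113 and 9, and 0 and 989 (523 higher, 466 lower). By camera the CRE interaction called 73 of 179 pairs of a list and a class and the FLPO interaction 69, and with an estimated correlation each called 0 (5 and 11 under an unadjusted p of 0.05). The CRE interaction ranked the type I interferon response lower in J2 in 8 classes, the interferon gamma response and oxidative phosphorylation lower in 7, glycolysis lower in 6 and heat shock higher in 6. Of these calls 5 stayed for type I interferon without GFP_J1 replicate 1, 1 for oxidative phosphorylation and 3 for glycolysis without CRE_J1 replicate 2, and 3 for heat shock without CRE_J2 replicate 2. The FLPO interaction ranked heat shock higher and the interferon gamma response lower in 7 classes each, of which 5 stayed for heat shock without FLPO_J1 replicate 2 and 1 for the interferon gamma response without GFP_J2 replicate 1. By fry the interactions called 1 and 0.

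Monocyte-derived macrophages took 1.71% ± 0.190 (SD, n = 2) of the kept cells of CRE_J2. They took 7.70% ± 1.10 of GFP_J2 and 8.20% ± 2.13 of FLPO_J2, and 6.41% ± 1.87 of CRE_J1, 2.995% ± 0.756 of GFP_J1 and 3.16% ± 1.05 of FLPO_J1 (each SD, n = 2). The CRE interaction of this share was -3.26 on the log2 scale (SE 0.53, adjusted p = 7.30e-04), a test added after the data were seen. Within J2 the difference was -2.16 for CRE minus GFP (SE 0.38, adjusted p = 0.0015) and 2.26 for FLPO minus CRE (SE 0.39, adjusted p = 0.0011), and within J1 no class passed for CRE minus GFP (lowest adjusted p = 0.115). Erythroid cells also had a CRE interaction, 3.00 (SE 0.74, adjusted p = 0.011), but the libraries of GFP_J2 held only 1 and 2 of these cells and those of CRE_J2 4 and 9. This call ended without GFP_J2 replicate 1 (2.46), without CRE_J2 replicate 2 (2.68) or without both interferon-high libraries (2.06). In J1, plasma cells of FLPO were 1.99 above GFP_J1 (adjusted p = 0.031) and 2.39 above CRE_J1 (adjusted p = 0.0096). In J1, neutrophils and monocytes were lower in FLPO than in CRE by -1.08 (adjusted p = 0.028) and -1.20 (adjusted p = 0.018). The call of plasma cells against CRE_J1 ended without CRE_J1 replicate 2 (1.81), and that against GFP_J1 without either GFP_J1 library, either FLPO_J1 library or either CRE_J2 library (1.82 to 2.19). The call of neutrophils ended without either GFP_J1 library, CRE_J1 replicate 2 or FLPO_J1 replicate 2 (-1.08 to -0.83), and that of monocytes without CRE_J1 replicate 2 (-0.83) or FLPO_J1 replicate 2 (-1.10). With the replicate number as a block, only the call of plasma cells against CRE_J1 stayed.

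The 9 clusters without a class held 3.74% of GFP_J1, 5.19% of CRE_J1, 3.48% of FLPO_J1, 5.20% of GFP_J2, 6.99% of CRE_J2 and 9.42% of FLPO_J2. Cluster 20 carried Foxp3, Ctla4 and Ikzf2, genes of regulatory T cells, and took 0.946% to 1.98% of a group. Cluster 18 carried the Kupffer cell genes C1qa and Apoe with a median of 1076 UMIs per cell, and took 6.09% of FLPO_J2 (0.616% and 11.6% in its libraries) and 0.317% to 1.53% of the other groups. It had fewer than 3 raised markers of a class. Clusters 23 and 28 carried Klra receptor genes of NK cells together with the Cd3 genes of T cells, and a rule on Cd3 genes set after the data were seen kept them out of NK/ILC1. Cluster 23 took 0.591% to 1.31% of a group, and cluster 28 1.97% of GFP_J2 (3.29% and 0.647% in its libraries), 1.96% of CRE_J2 (2.98% and 0.943%) and 0.2% to 0.626% of the other groups. Clusters 35, 40, 44, 46 and 47 each took at most 0.464% of a group; a rule on doublet scores, also set after the data were seen, kept out 40, 44 and 46.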

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

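Of the tests below, those that left out the genes of red cells and hepatocytes, the count of monocytes and macrophages together, the size of the neutrophil changes in thinned sums, and all interaction tests of shares were chosen only after the results were seen.

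In all 8 classes 19 genes were more than 4-fold lower in J2 than in J1. They include the ribosomal genes Rps27 (median over the classes -7.30), Rpl10 (-6.87), Rpl9 (-5.15), Rpl35 and Rpl36a (-2.22), Gapdh (-3.01) and Rnaset2a (-2.62), and the hemoglobin genes Hba-a1 (-6.47), Hba-a2, Hbb-bs and Hbb-bt. Depth stays open, since thinning all libraries to the same total keeps gene shares (median change of the 19 in B cells -5.06, thinned -5.13). A near-identical copy was present for 15 of the 19 (78.9%, exact 95% interval 54.4% to 93.9%). Of the other genes 9.34% had one, a ratio of 8.45. Counting of shared reads may explain part of the pattern, but 505 genes with a copy were not among the 19. Red blood cell RNA in J1 stays open for part of it, since the 15 genes among them that do not encode hemoglobin made up at most 3.85 times the share of non-hemoglobin UMIs in red-cell barcodes that they made up in B cells. The 8 genes of neither red cells nor hepatocytes were at 0.372 of their B cell share there, which decides nothing, since they were sorted by that share. Of these 8 of 8 had a copy, a ratio of 10.7. This sorting of the genes was made after their values were seen, and a first version of the red-cell ratio counted hemoglobin in one part only and was corrected after it was seen. Whether the suffix also stands for a biological difference in these genes was not tested.

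Thbs1 (-4.53) and Basp1 (-2.69) in neutrophils differed between the suffixes in their CRE minus GFP change, as did 121 genes over all classes, of which 108 were in neutrophils. Free RNA stays open, as the 108 genes were chosen and signed in neutrophils. Their median interaction was 1.84 there and 0.10 (B cells) to 0.47 (Kupffer cells) elsewhere. A different mix of neutrophils cannot be told apart from a change within them: without cluster 16 the median was 0.65, 35.5% of its value, and 0 of the 98 genes still tested were called, but the cells of cluster 16 stand out by genes of the pattern itself (4 of its 10 leading genes are called), so leaving them out lowers the pattern under either explanation. Depth stays open, as thinning keeps gene shares. With sums thinned to the same total the median was 1.78 (quartiles 1.37 to 2.40), and all 106 genes still tested kept their direction. Of the 108, 72 were still called; the others had a median of 1.52 (median SE 0.38) against 1.80 (0.35) before. A biological difference between title labels that depends on the suffix also stays open and was not tested further.

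Monocyte-derived macrophages differed between the suffixes in the CRE minus GFP change of their share, by -3.26. Other barcodes in the denominator were argued against, since over leukocyte classes alone the interaction was -3.29. Cells named monocyte instead were argued against as the whole cause, since monocytes and macrophages counted together gave -1.58 (SE 0.45), although that is smaller than the change of the macrophages alone. A mislabelled library was not tested, and both CRE_J2 libraries, at 1.58% and 1.85%, lay below the other 10. A biological difference in these macrophages may therefore be a candidate explanation, as a hypothesis found and tested on the same 12 libraries.

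The other results that differed between the suffixes were these. The erythroid share had a CRE interaction of 3.00. In NK/ILC1 the CRE interaction was 3.08 for Atp8a2 and -2.93 for Cx3cr1. In Kupffer cells it was 3.49 for Igkc. In monocyte-derived macrophages it was 1.64 for Tfec and 3.54 for Syne1. In conventional dendritic cells it was 4.23 for Hbb-bs. By camera 73 pairs of a list and a class were called in the CRE interaction and 69 in the FLPO interaction, none of them with an estimated correlation. The FLPO interaction called 3 genes, Gm47283 in NK/ILC1 (-1.98) and Hbb-bs (4.47) and Mmp25 (-1.93) in conventional dendritic cells.

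Single libraries lay far from the other 5 of their suffix in 11 of 76 sets of values tested, where about 5% would by chance. CRE_J1 replicate 2 stood out with 40.8 CPM of Mapk9 and with the mean log2 level of the interferon gamma response (7.06), glycolysis (6.57) and oxidative phosphorylation (7.27). CRE_J1 replicate 1 had the lowest share of T cells in J1, 17.8%. GFP_J1 replicate 2 had the highest red blood cell RNA in J1 (12.2). GFP_J2 replicate 1 stood out with 44.7 CPM of Mapk9, MHC class II (7.02) and inflammatory cytokines and NF-kB targets (5.83). CRE_J2 replicate 2 had the lowest share of hepatocytes in J2, 0.0510%, and the highest red blood cell RNA in J2 (6.72).

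For the counts of called genes, other splits of the same libraries were tried in an additive model, fitted for each pair of title labels to the 8 libraries of that pair alone, so the real counts below differ from those reported. For J2 minus J1 chance can be excluded: the real split called 28336 genes and the highest of the other 59 called 3084, with 1 of 60 splits as large. For CRE minus GFP the real split called 0, so every split is as large and there was no count to test (highest other 17047). Chance cannot be excluded for FLPO minus GFP (10 called against 1 reported, highest other 20801, 8 of 35) or FLPO minus CRE (2 called against 6 reported, highest other 22861, 11 of 35). The highest counts came from the splits that part J1 from J2, which points to the suffix as a structure of the samples.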

How the results depend on the processing

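The fits without both interferon-high libraries (CRE_J1 replicate 2 and GFP_J2 replicate 1), the tests of shares within and between suffixes and the shuffled library orders were chosen after the data were seen. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Except where the way an alternative was built is given as a reason, the cause of a change was not tested.

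Counts of called genes depended on the test and on single libraries. CRE minus GFP went from 0 to 32 with DESeq2, 1158 with no filter on low counts, 3 at Leiden resolution 2.0 and 2 without the interferon-high libraries. Leaving out 1 library gave 0 to 190, with 190 and 5 without CRE_J1 replicates 1 and 2, 14 without CRE_J2 replicate 1, and 1 without either FLPO_J1 library or GFP_J1 replicate 1. FLPO minus GFP went from 1 to 66 with DESeq2, 1102 with no filter, 0 with the additive model, 0 with doublets kept, 2 at resolution 2.0, 2 with the replicate block and 7 without the interferon-high libraries. Leaving out 1 library gave 1 to 6, with 2 without either CRE_J1 library, 6 without either CRE_J2 library, 3 without GFP_J1 replicate 1 and 5 without GFP_J2 replicate 2. FLPO minus CRE went from 6 to 345 with DESeq2, 3229 with no filter, 12 with the block, 15 with the stricter cell filter and 20 without the interferon-high libraries. Leaving out 1 library gave 1 to 888, with 13 without CRE_J2 replicate 2, 2 and 1 without FLPO_J1 replicates 1 and 2, 3 without FLPO_J2 replicate 2 and 2 without either GFP_J1 library. The CRE interaction went from 121 to 482 with DESeq2, 3557 with no filter and 211 without the interferon-high libraries, and from 7 to 703 without 1 library. The FLPO interaction went from 3 to 46 with DESeq2, 1161 with no filter, 6 at resolution 2.0, 12 with the block and 7 without the interferon-high libraries, and from 0 to 13 without 1 library. J2 minus J1 stayed within 1.5 times in all 22 alternatives, at 23801 to 32636, and at 24366 to 29804 without 1 library. Averages over both suffixes cannot be formed in fits of J1 or J2 alone. There CRE minus GFP called 25 in J1 and 155 in J2 (19 and 194 in the joint fit), FLPO minus GFP 51 and 5 (29 and 2) and FLPO minus CRE 5 and 170 (7 and 187).

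Of 995 values, under the alternatives, of 46 named results (a gene in a class and a contrast), 889 kept their direction and side of the threshold, 106 kept the direction alone and 0 reversed. The 30 named for J2 minus J1, and the interactions of Thbs1, Basp1 and Atp8a2, passed in every alternative run; leaving out cluster 16, a test of the cell mix, ended the calls of Thbs1 (-2.23) and Basp1 (-0.87).

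At resolution 0.5 no cluster was named monocyte-derived macrophage, so its share, Tfec and Syne1 have no value there. In the 19 alternatives with that class its share passed: the CRE interaction lay from -3.77 to -2.77, CRE minus GFP in J2 from -2.58 to -2.01 and FLPO minus CRE in J2 from 1.96 to 3.00. For J2 minus J1, 4 to 7 classes passed. Plasma cells lost their call over leukocytes alone (0.67, adjusted p = 0.132) and with stricter cells (0.79, adjusted p = 0.0623), and lay from 0.66 to 1.18 without 1 library. FLPO minus CRE gave 1 class at resolution 2.0 and 0 to 3 without 1 library (3 without CRE_J1 replicate 1, 2 without FLPO_J2 replicate 2). FLPO minus GFP gave 0 to 1 (1 without FLPO_J2 replicate 2), and CRE minus GFP 0 in all 21.

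List calls fell to 0 with an estimated correlation in CRE minus GFP, FLPO minus GFP, FLPO minus CRE and J2 minus J1. Fry called 0 in all but the last (80). The estimated correlation, mostly larger than the preset one, missed even red blood cell RNA in J2, so 0 calls decide little. In shuffled library order camera did not change and the estimated correlation still called 0. Fry called 77 to 80 for J2 minus J1 and 0 to 1 for the CRE interaction. Without 1 library camera called 31 to 63, 39 to 70, 51 to 79 and 69 to 84.

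In class sums Mapk8 reversed for CRE minus GFP in neutrophils (0.30) and monocyte-derived macrophages (0.015). For FLPO minus GFP Mapk8 reversed in NK/ILC1 (0.12), neutrophils (0.42), monocytes (0.069), Kupffer cells (0.064), monocyte-derived macrophages (0.17) and conventional dendritic cells (0.085), and without FLPO_J2 replicate 1 (0.011). Its J2 minus J1 rise lost its call in NK/ILC1 (0.31), neutrophils (0.36) and Kupffer cells (0.11). Mapk9 reversed for CRE minus GFP in B cells (-2e-04), T cells (-0.042), NK/ILC1 (-0.17) and conventional dendritic cells (-0.042). For FLPO minus GFP it reversed in NK/ILC1 (0.091), Kupffer cells (0.022) and monocyte-derived macrophages (0.042), and for FLPO minus CRE in NK/ILC1 (0.26) and conventional dendritic cells (0.033). For J2 minus J1 Mapk9 passed in T cells (0.28, adjusted p = 0.0017) and reversed in neutrophils (-0.0595), monocytes (-0.0313) and monocyte-derived macrophages (-0.0895). Without 1 library Mapk8 lay from -0.25 to -0.13, -0.064 to 0.011, 0.11 to 0.23 and 0.50 to 0.58 for CRE minus GFP, FLPO minus GFP, FLPO minus CRE and J2 minus J1. Mapk9 lay from -0.068 to 0.083, -0.13 to 0.014, -0.13 to 0.0043 and 0.046 to 0.15. Mapk9 reversed for CRE minus GFP without GFP_J1 replicate 1 (-0.0077), CRE_J1 replicate 2 (-0.068), FLPO_J1 replicate 1 (-0.0029), GFP_J2 replicate 2 (-0.065) and CRE_J2 replicate 2 (-0.0089), for FLPO minus GFP without GFP_J2 replicate 1 (0.014) and for FLPO minus CRE without CRE_J1 replicate 2 (0.0043). DESeq2 gave no adjusted p for Mapk8 and Mapk9 in CRE minus GFP.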

Other observations

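The test of heat shock genes below was chosen before its result was seen, and the genes named here were chosen after their values were seen. The 2 libraries of GFP_J1 were the highest of the 12 for the heat shock list in 8 of 8 classes, and for immediate early/AP-1 genes in 0 of 8. In B cells Hspa1a, the stress-inducible Hsp70, averaged 76.3 CPM ± 7.11 (SD, n = 2) in GFP_J1, and its CRE minus GFP change within J1 was -4.11 (adjusted p = 0.00845). Handling of these libraries could raise such genes in every class alike, but so could a condition of the group, and with both libraries of 1 group high the 8 classes cannot be told apart from a group effect.

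Igha, the constant part of the IgA antibody, was higher in B cells of FLPO_J1 than of GFP_J1 by 2.05 on the log2 scale (adjusted p = 0.00336). In the same libraries plasma cells took 1.84% ± 0.0176 (SD, n = 2) and 0.463% ± 0.0828 (SD, n = 2) of the kept cells. Retnlg, a marker of mature neutrophils, had a CRE interaction of 0.18 in neutrophils that did not pass (adjusted p = 0.850), unlike Thbs1 and Cxcl2.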
